A study of Mus musculus with 24 samples.

How the data were processed

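Total RNA of 5 oocytes or embryos per sample was taken up in lysis buffer and made into complementary DNA with the SMART-Seq HT kit, per the labels. The series holds 24 libraries of wild-type and Nlrp14 knockout mice, 3 per genotype at each of 4 stages. One file per library was used, in which the authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 55487 Ensembl genes. Per the submitters' processing notes, StringTie and the mouse genome build GRCm38 were used. The versions, the aligner, the annotation release and any filters were not given in the sources used here. No scaling between libraries beyond FPKM was stated, and summed FPKM ran from 306296.2 to 534726.9. Groups and replicate numbers were taken from the sample labels. No pair of libraries held identical values.

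Gene symbols, positions and exon lengths came from the GENCODE M21 annotation of GRCm38, which matched 55227 of the 55487 identifiers, and 260 stayed without a symbol. FPKM values carry depth when fragments are counted whole. For the 34257 genes with 1 annotated transcript, FPKM times length came in whole multiples of one step per library for 98.83 to 99.21% of low values (multiples up to 30, tolerance 0.02). The steps gave 7.65 to 12.3 M fragments per library, so that 1 fragment in a gene of 1 kb was worth 0.0814 to 0.131 FPKM. Values near that level rest on single fragments. Genes with several transcripts do not give whole fragments, so no count model was applied, and the test planned for normalized values was used.

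Each comparison was fitted with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8, on log2(FPKM + 1), with a mean for each group in the comparison and an empirical Bayes variance with trend and robust settings. Genes with at least 1 FPKM in at least 3 libraries of the fit were tested. A gene was called when its p, adjusted by the method of Benjamini and Hochberg, was under 0.05. The comparisons were knockout against wild type at each stage, the changes between successive stages in wild type, and the interaction of genotype with each such change. Figures and annotation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

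The 20 gene lists, the comparisons, the rule for named genes and the other settings tried were fixed before the data were examined, apart from those named as added later. The lists covered the subcortical maternal complex (8 genes), the oocyte NLRP family (11), oocyte identity (27), DNA methylation and imprint maintenance (17), calcium handling (32), the proteasome (34), maternal mRNA storage and clearance (27), 2-cell-specific genes (35) and embryonic transcription factors (23). They also covered ribosome biogenesis (46), cytosolic ribosomal proteins (79), mitochondrially encoded proteins (13), nuclear oxidative phosphorylation (62), p53 targets and apoptosis (23), antioxidant defence (22), the unfolded protein response (22) and the meiotic and mitotic cell cycle (36). Markers of granulosa and cumulus cells (24), of sperm and spermatids (18) and of blood, stroma and oviduct (15) stood for other cell types. Nlrp14 was left out of all lists. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 69 tests of a list at a stage, and again with an estimated correlation and with fry.

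The rule for named genes took Nlrp14 in every library. At each stage it took the 8 largest rises and 8 largest falls among called genes with all knockout libraries on one side of all wild-type libraries and at least 5 FPKM in the higher group, leaving out predicted genes, Rik genes, pseudogenes and genes without a symbol. Groups of 3 and 3 separate in this way in 10% of cases by chance. It took up to 4 members of each list by smallest p, the members past the threshold where 3 or fewer passed, and Slc8b1 and Uhrf1 at each stage. For wild-type changes it took 5 genes per direction and for interactions 4.

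For stage genes held out from one library, genes changing at least 2-fold between stages were defined in wild type without that library and compared between it and the knockout. Overlaps of calls were set against the product of the list sizes over the number of genes tested in both. The fit was tested on simulated data with 67, 67 and 66 genes changed 2-, 4- and 8-fold. It recovered 28.4, 94.0 and 98.5% of them at GV (11909 genes, 11 false calls), 64.2, 95.5 and 100% at MII (9095 genes, 10 false calls), 13.4, 86.6 and 98.5% at PN5 (9849 genes, 15 false calls) and 5.97, 76.1 and 95.5% at the 2-cell stage (15132 genes, 8 false calls). With no gene changed it called 0 at GV and PN5 and 1 at MII and at the 2-cell stage. The changed genes were drawn from those with a wild-type mean of at least 5 FPKM. The simulated noise was independent between genes, without the length trends or shifts that genes of a real library share. These rates therefore need not hold for the real comparisons.

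The other settings tried were median-of-ratios rescaling, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, limma without trend and robust settings, a 2-fold threshold, the replicate number as a block, all 24 libraries in one fit and leaving out each library in turn. With 1 library left out, a gene at 1 FPKM or more only in that library's group could no longer reach 3 libraries. Such genes were then not tested. Removal of each library's trend of level with length (lowess, span 0.5) and rescaling to TPM were added after seeing the data.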

Results

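RNA sequencing was used to compare oocytes and embryos of wild-type mice with those of Nlrp14 knockout mice, in a study of female infertility and early embryo arrest. NLRP14 is an NLR family protein with a pyrin domain that is made in oocytes. Each library came from 5 oocytes or embryos at 1 of 4 stages: germinal vesicle (GV) oocytes, metaphase II (MII) oocytes, late pronuclear (PN5) zygotes and 2-cell embryos. Each stage had 3 wild-type and 3 knockout libraries, labelled as biological replicates, which makes 24 libraries in 8 groups. The genotype of the males that sired the embryos was not given in the sources used here. Depth implied by the deposited values lay between 7.65 and 12.3 M fragments per library. It was 8.56 ± 1.05 M (SD, n = 3) in wild-type and 7.99 ± 0.21 M in knockout 2-cell embryos. Between 11736 and 12037 genes reached 1 FPKM in the knockout 2-cell libraries, against 14128 to 14561 in wild type. Pairs of values give wild type first and knockout second, as mean FPKM ± SD of 3 libraries. Changes are log2 differences of FPKM + 1 (knockout minus wild type) with their standard error (SE), a scale that understates the change of genes with low values. For gene lists, a count over all tested genes stands beside the count adjusted over the list alone. The p-values measure the spread between these libraries, each a pool of oocytes or embryos.

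Nlrp14 itself was measured first, since it checks the labels. In GV oocytes it stood at 1876, 2014 and 1922 FPKM in the 3 wild-type libraries and at 22.2, 23.7 and 39.2 FPKM in the knockout libraries. At MII the values were 380.4, 447 and 345 against 14.6, 22.9 and 21.3 FPKM. At PN5 they were 169, 243 and 217 against 6.17, 8.48 and 5.75 FPKM. At the 2-cell stage they were 90.2, 129 and 99.0 FPKM in wild type and 25.9, 36.2 and 17.2 FPKM in the knockout. The knockout mean was 1.46% of wild type at GV, 5.02% at MII, 3.24% at PN5 and 24.9% at the 2-cell stage, and every knockout library lay below every wild-type library of its stage. The log2 differences were -6.09 at GV (SE 0.23, adjusted p = 0.00027), -4.26 at MII (SE 0.20, adjusted p = 9.5e-05), -4.76 at PN5 (SE 0.23, adjusted p = 0.00027) and -2.01 at the 2-cell stage (SE 0.28, adjusted p = 0.00082). The gene (ENSMUSG00000016626) is annotated as protein coding on chromosome 7 of GRCm38 (107166990 to 107198102, + strand), with 2 transcripts and 3537 nt of exon sequence. Which part of it was deleted was not given in the sources used here, and a gene-level FPKM does not separate exons.

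**Figure D1:**
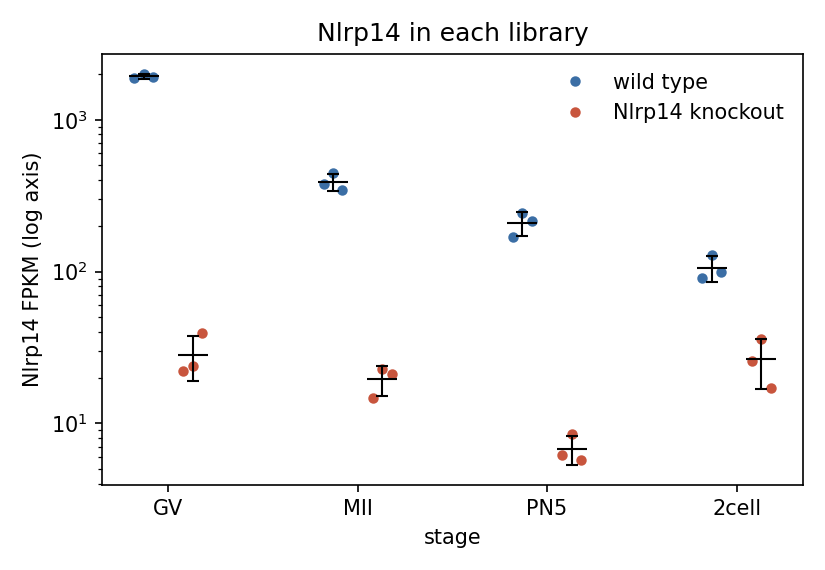
Nlrp14 expression in each library (dots, FPKM on a log axis) for wild-type and knockout samples at the GV, MII, PN5 and 2-cell stages, with the mean and SD of 3 libraries. The knockout dots lie below the wild-type dots at every stage, and the knockout mean is 6.80 FPKM at PN5 and 26.4 FPKM at the 2-cell stage.

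In GV oocytes few genes differed between genotypes. Apart from Nlrp14, 4 of the 11635 tested genes passed the test. Zglp1, a GATA-like transcription factor that acts in the oogenic programme, fell from 5.08 ± 0.676 to 0.189 ± 0.0405 FPKM (log2 -2.35, SE 0.15, adjusted p = 0.0046). Gm49373 rose from 0.635 ± 0.203 to 7.57 ± 1.05 FPKM (log2 2.39, adjusted p = 0.0094). Zglp1 (21062393 to 21067093) and Gm49373 (21062400 to 21073096) overlap on the - strand of chromosome 9, so the division of reads between them is uncertain. The pseudogene Olfr650-ps1 fell from 8.66 ± 0.695 to 1.57 ± 0.224 FPKM (log2 -1.91, adjusted p = 0.016). The long noncoding RNA Gm30564 fell from 7.0 ± 1.15 to 1.19 ± 0.251 FPKM (log2 -1.87, adjusted p = 0.041). Gm49373, Olfr650-ps1 and Gm30564 were named after their values were seen. Olfr650-ps1 lies on chromosome 7 (104203437 to 104207865), within 10 Mb of Nlrp14, and was the only one of 102 tested neighbours in that window to pass (Fisher's exact test against the other tested genes without Nlrp14, two-sided, p = 0.035). This window test was not among the comparisons fixed in advance, and at GV it rests on that 1 gene. In the same window 1 of 76 genes passed at MII (exact p = 1), 3 of 86 at PN5 (exact p = 0.49) and 73 of 132 at the 2-cell stage (exact p = 0.86). The number of genes called at GV was 1 without any one of the wild-type libraries, 3 without knockout replicate 1 or 2 and 1026 without knockout replicate 3. It was 1 with a mean of at least 5 FPKM, 2 with no filter, 35 with the length trend removed and 197 with all 24 libraries in one fit.

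Among the gene lists at GV, camera placed ribosomal protein and oxidative phosphorylation genes slightly higher in the knockout as sets. Fry called neither (adjusted p = 0.39 and 0.24). No single member passed over all genes (limma, with 1378 of all tested genes at an unadjusted p under 0.05). Of 76 tested cytosolic ribosomal protein genes 71 were positive, with a median of 0.25 and a summed level of 2369 ± 67.0 to 2847 ± 666 FPKM. Camera gave adjusted p = 6.1e-10 for this list, and adjusted p = 0.834 with an estimated correlation. The call was lost without knockout replicate 3 (adjusted p = 0.0526), the library whose levels were most tilted towards short genes (slope of log2 level on log2 length -0.13, against 0.00 to 0.04 in the other GV libraries). Of 62 nuclear genes of oxidative phosphorylation 53 were positive, with a median of 0.25 (camera adjusted p = 8.8e-09, and adjusted p = 0.834 with an estimated correlation). Ndufb8, a subunit of complex I, read 15.0 ± 0.928 to 23 ± 3.30 FPKM (adjusted p = 0.23). Of 17 antioxidant genes 13 were positive (camera adjusted p = 0.040, and adjusted p = 0.834 with an estimated correlation), among them the peroxiredoxin Prdx1 at 419.9 ± 8.28 to 807 ± 301 FPKM (adjusted p = 0.24). The antioxidant call was lost after median-of-ratios rescaling (0.072) or length correction (0.062), without wild-type replicates 1 (0.092), 2 (0.0583) or 3 (0.108) and without knockout replicates 2 (0.0523) or 3 (0.190). Adjusted over the list alone, 1 of 11 oocyte NLRP genes was lower (Nlrp4g, 65.9 to 31.6 FPKM, adjusted p over all genes = 0.13). Of 3 sperm markers, Ldhc was higher and Prm2 lower adjusted over the list alone. No member of the other 18 lists passed in either count at GV, and camera called no list beyond the 3 above.

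In MII oocytes the transcripts encoded by mitochondrial DNA lay higher in the knockout. All 13 protein-coding transcripts of this set were higher in the knockout, 2 of them past the threshold over all genes and 13 adjusted over the list alone. Their summed level was 18025 ± 1767 FPKM in wild type and 28598 ± 3839 FPKM in the knockout (n = 3 each). The complex I subunit mt-Nd4 rose from 974.7 ± 147 to 1669 ± 106 FPKM (log2 0.79, SE 0.15, adjusted p = 0.041). The subunit mt-Nd1 rose from 2132 ± 204 to 3342 ± 142 FPKM (log2 0.65, adjusted p = 0.041). The median of the set was 0.65 as deposited and between 0.48 and 0.92 under the 3 other scalings, with all 13 members positive in each. Over all genes, limma called 1 of the 13 after median-of-ratios rescaling (mt-Nd1 had adjusted p = 0.0520), 2 with the length trend removed and none as TPM (0.0508 for mt-Nd4 and 0.0530 for mt-Nd1, with 2997 of all tested genes at an unadjusted p under 0.05). For the set, camera gave adjusted p = 1.9e-13, and adjusted p = 0.834 with an estimated correlation. Mitochondrial transcripts made up 6.33 to 7.48% of summed FPKM in wild-type and 9.04 to 9.72% in knockout MII libraries. The same libraries also separated by the sum of the granulosa and cumulus markers, 180.2 to 187 FPKM in wild type and 217 to 228 FPKM in the knockout. Nearly all of that sum came from the only 2 of the 24 markers that reached the filter (182 ± 3.33 to 221 ± 4.26 FPKM). Neither passed in either count, so the sum does not speak for the marker list as a whole. The slope of log2 level on log2 length was 0.03, -0.10 and -0.04 in knockout MII replicates 1, 2 and 3 and 0.02 to 0.04 in wild type.

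At MII, 199 of 8739 tested genes differed, 28 higher and 171 lower (85.9% lower). The largest rise was in Smap1, an ARF GTPase-activating protein of clathrin-dependent traffic (3.17 ± 0.906 to 14.7 ± 5.52 FPKM, log2 1.88, SE 0.28, adjusted p = 0.020). Mtus1, a microtubule-associated protein, rose from 5.88 ± 0.365 to 19.9 ± 4.42 FPKM (log2 1.59, adjusted p = 0.014), and the basic helix-loop-helix factor Tcf15 from 2.75 ± 1.46 to 9.61 ± 2.87 FPKM (log2 1.54, adjusted p = 0.042). The interferon-induced membrane protein gene Ifitm3 rose from 120.0 ± 8.37 to 273 ± 46.7 FPKM (log2 1.17, adjusted p = 0.017). AC132253.6 (log2 1.53), Dirc2 (1.42), the helix-loop-helix inhibitor Id3 (1.26) and Tmem243 (1.26) also rose. The largest fall after Nlrp14 was in Cdc42ep3, an effector of the small GTPase CDC42 (11.4 ± 2.75 to 1.06 ± 0.169 FPKM, log2 -2.57, SE 0.21, adjusted p = 0.0043). The complex I subunit Ndufa1 fell from 19.8 ± 5.02 to 3.91 ± 0.984 FPKM (log2 -2.07, adjusted p = 0.013). The calcium-binding protein Gca (6.04 to 0.586 FPKM, log2 -2.14), Cyp4v3 (10.1 to 1.97 FPKM, -1.91), Zfp961 (22.5 to 5.32 FPKM, -1.83) and Pebp1 (11 to 2.49 FPKM, -1.76) fell too, with adjusted p from 0.0043 to 0.021. The phosphatase Ptp4a1 fell from 50.6 to 12.6 FPKM (log2 -2.01), which is uncertain because a second model carries the same symbol (the one here is ENSMUSG00000026064). The median tested gene was shifted by -0.18 as deposited, by 0.03 after median-of-ratios rescaling and by -0.37 as TPM. Median-of-ratios rescaling gave 65 calls (64.6% lower, 59 shared with the 199), removal of the length trend 128 (70.3% lower, 110 shared) and no filter on low values 8, all shared. Across genes, which are not independent, the log2 difference at MII fell with length (Spearman rho -0.29), and the median length was 1456.5 nt for the higher, 2484 nt for the lower and 3172 nt for all tested genes. Leaving out 1 library gave 3 calls (wild-type replicate 1), 12 (wild-type replicate 2 or 3), 3083 (knockout replicate 1), 81 (knockout replicate 2) or 13 (knockout replicate 3).

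The maternal lists changed little at MII. In the oocyte identity list, 1 of 25 genes fell over all genes, the zona pellucida gene Zp3 (85.8 ± 2.70 to 50.6 ± 6.70 FPKM, log2 -0.76, adjusted p = 0.043). Adjusted over the list alone, 3 of these genes were higher and 3 lower. None of the 8 genes of the subcortical maternal complex passed over all genes, and 2 were lower adjusted over the list alone. Of this complex, Tle6 stood at 33.5 to 17.3 FPKM (adjusted p = 0.069) and Nlrp5 at 49.5 to 33.2 FPKM (adjusted p = 0.087). Among 18 calcium genes the reticulum pump Atp2a2 fell in both counts (39.9 ± 1.72 to 23.5 ± 1.89 FPKM, log2 -0.74, adjusted p = 0.041). Among 8 p53 targets Btg2 fell (7.79 to 3.74 FPKM, log2 -0.90, adjusted p = 0.042), and among 16 antioxidant genes Nfe2l2, their regulator, fell (14.9 to 6.88 FPKM, log2 -1.02, adjusted p = 0.022). In each of these last lists 1 gene was higher and 1 lower adjusted over the list alone. The Zp3, Atp2a2, Btg2 and Nfe2l2 calls were lost after median-of-ratios rescaling (adjusted p from 0.065 to 0.125) and with the length trend removed (0.0515 to 0.083). In the DNA methylation list 1 of 12 genes was higher and 3 were lower adjusted over the list alone, and in the 2-cell-specific list 1 of 4 was lower, with none in either list over all genes. Camera placed ribosomal proteins higher (29 tested, 21 positive, adjusted p = 0.0037, and adjusted p = 0.834 with an estimated correlation), with 1 member higher and 2 lower adjusted over the list alone. That call was lost without knockout replicate 2 (0.0998). Camera also placed the 44 tested oxidative phosphorylation genes higher (adjusted p = 0.048, and adjusted p = 0.834 with an estimated correlation), although their mean was -0.00 and Ndufa1, the single member that passed, fell. Their median was 0.09 as deposited and -0.06 as TPM, and the call was lost under the 3 other scalings (0.065 to 0.288) and without wild-type replicate 1 (0.0521), wild-type replicate 3 (0.186) or knockout replicate 2 (0.404). Fry called neither the ribosomal protein nor the oxidative phosphorylation list (adjusted p = 0.64 and 0.99). It placed the embryonic transcription factor and ribosome biogenesis lists lower instead (adjusted p = 0.0076 and 0.047). Camera compares a list with the other tested genes, so a list can be placed higher while its own mean lies below 0. Camera called no other list at MII (adjusted p from 0.13 to 0.999), and the NLRP, proteasome, mRNA clearance, embryonic transcription factor, ribosome biogenesis, unfolded protein response, cell cycle, granulosa and blood lists had no member in either count.

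In PN5 zygotes the oxidative phosphorylation and ribosomal protein lists lay lower in the knockout as sets, although few of their members passed over all genes. Of 47 nuclear oxidative phosphorylation genes 6 fell over all genes, and adjusted over the list alone 24 were lower and 1 higher (median -0.65). Camera gave adjusted p = 1.2e-06 for the list, and adjusted p = 0.834 with an estimated correlation. The complex I subunit Ndufa1 fell from 18.7 ± 1.78 to 1.62 ± 0.376 FPKM (log2 -2.91, SE 0.22, adjusted p = 0.0040). Ndufs5 (10.4 to 2.08 FPKM, log2 -1.79), Cox5b (22.1 to 9.24 FPKM, -1.16) and Cox7a2 (76.5 to 29.5 FPKM, -1.33) fell with adjusted p from 0.036 to 0.037. Of 33 ribosomal protein genes 4 fell over all genes and 10 were lower adjusted over the list alone (median -0.54). For them, camera gave adjusted p = 3.7e-05, and adjusted p = 0.834 with an estimated correlation. Rpl32 fell from 26.5 ± 9.16 to 6.94 ± 0.585 FPKM (log2 -1.74, SE 0.27, adjusted p = 0.034), and Rpl17 (41.0 to 13.7 FPKM), Rplp2 (30.3 to 12.1 FPKM) and Rpl39 (1.29 to 0.248 FPKM) fell too. These genes are short, and the PN5 libraries differed by length. The slope of log2 level on log2 length was -0.17, -0.07 and 0.02 in wild-type replicates 1, 2 and 3 and 0.06 to 0.09 in the knockout. They differed by GC content as well, for which no correction was tried. Per 10 percentage points of GC the slope was -0.38, -0.07 and 0.05 in wild-type and 0.15, 0.18 and 0.07 in knockout replicates 1, 2 and 3. The medians of these lists were -0.64 and -0.53 after median-of-ratios rescaling, -0.50 and -0.42 as TPM and -0.42 and -0.19 with the length trend removed. Under each of these 3 scalings limma called 1 oxidative phosphorylation gene and no ribosomal protein gene over all genes, with 2254 to 3255 of all tested genes at an unadjusted p under 0.05. Across genes, which are not independent, the log2 difference rose with length at PN5 (Spearman rho 0.41), and the median length was 1170.5 nt for the lower, 4221.5 nt for the higher and 3120 nt for all tested genes.

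At PN5, 578 of 9483 tested genes differed, 54 higher and 524 lower (90.7% lower). The largest rises were in Tcf15 (2.60 ± 2.34 to 17.1 ± 4.88 FPKM, log2 2.63, SE 0.60, adjusted p = 0.0462) and the splicing factor Srsf4 (5.30 ± 5.10 to 24.9 ± 3.38 FPKM, log2 2.38, adjusted p = 0.047). Plat, tissue plasminogen activator, rose from 46.6 ± 19.5 to 186 ± 55.5 FPKM (log2 2.00, adjusted p = 0.035). Kif2a, a microtubule-depolymerising kinesin, rose from 4.32 ± 0.326 to 19.7 ± 2.08 FPKM (log2 1.96, SE 0.21, adjusted p = 0.018). Tmco6 (1.37 to 9.04 FPKM), Fam69b (2.45 to 11.6 FPKM), the progranulin gene Grn (2.24 to 10.2 FPKM) and Ust (1.71 to 7.78 FPKM) rose with log2 differences from 1.73 to 2.18. The largest falls after Nlrp14 and Ndufa1 were in BC002163 (31.1 to 5.81 FPKM, log2 -2.17) and the oocyte-secreted Oosp2 (201 ± 106 to 45.9 ± 13 FPKM, log2 -2.02, adjusted p = 0.036). The thioredoxin gene Txn1 fell from 22.7 ± 6.89 to 5.08 ± 2.18 FPKM (log2 -1.99, adjusted p = 0.035). The small nucleolar RNA Snora47 (29.0 to 6.12 FPKM, log2 -2.00) and Sdhaf4, an assembly factor of complex II (39.8 to 11.1 FPKM, -1.87), fell too. The fall of the histone gene Hist1h2ao (9.23 to 1.61 FPKM, log2 -1.88) is uncertain because histone genes have near-identical copies. The median tested gene was shifted by 0.01 as deposited and by 0.23 as TPM. Only 15 genes were called after median-of-ratios rescaling (73.3% lower), 7 as TPM, 41 with the length trend removed (65.9% lower), 110 with a pseudocount of 0.1, 3 with no filter and 2491 with all 24 libraries in one fit. Leaving out 1 library gave 1 call (wild-type replicate 2, knockout replicate 1 or knockout replicate 3), 2 (knockout replicate 2), 616 (wild-type replicate 1) or 2967 (wild-type replicate 3). The excess of lower genes depended on the fit. Without wild-type replicate 3, 1439 genes were higher and 1528 lower. With all 24 libraries in one fit 849 were higher and 1642 lower, and without wild-type replicate 1 the split was 82 and 534.

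A few genes of the maternal and cell cycle lists passed at PN5, in both directions. In the oocyte identity list the egg protease gene Astl (5.86 ± 2.86 to 17.1 ± 2.14 FPKM, log2 1.48, adjusted p = 0.043) and the oocyte linker histone H1foo (1284 ± 80.9 to 2309 ± 298 FPKM, log2 0.84, adjusted p = 0.0462) rose. Oosp2 and the piRNA pathway gene Gtsf1 (14.1 to 6.08 FPKM, log2 -1.07) fell, so that 4 of 26 genes passed over all genes, and adjusted over the list alone 4 were higher and 2 lower. Of 32 cell cycle genes, the spindle checkpoint kinase Bub1b rose (91.0 ± 30.8 to 227 ± 51.9 FPKM, log2 1.33, adjusted p = 0.043) and the chromosomal passenger Birc5 fell (123 ± 10.6 to 61.6 ± 15.5 FPKM, log2 -1.02, adjusted p = 0.0454), in both counts. Of 33 proteasome genes, Psma1 (63.6 to 21 FPKM, log2 -1.51) and Psmb2 (118 to 37.9 FPKM, -1.66) fell in both counts. The mitochondrial channel gene Vdac2 fell (18.1 to 6.07 FPKM, log2 -1.41), 1 of 21 calcium genes over all genes and 3 adjusted over the list alone. The ribosome biogenesis gene Ebna1bp2 fell (10.1 to 3.53 FPKM, log2 -1.32), 1 of 28 over all genes and 3 adjusted over the list alone, and Txn1 was the 1 of 16 antioxidant genes that fell in both counts. Among 5 2-cell-specific genes Tcstv1 fell (53.1 to 17.1 FPKM, log2 -1.67), and 4 were lower adjusted over the list alone. Among 11 embryonic transcription factors Obox7 fell in both counts (456 to 169 FPKM, log2 -1.37). Both Tcstv1 and Obox7 have near-identical relatives and are uncertain. The calls of these 13 genes, from Astl to Obox7, were lost after median-of-ratios rescaling (adjusted p from 0.0565 to 0.081), as TPM (0.080 to 0.159) and with the length trend removed (0.0525 to 0.074). Adjusted over the list alone, 1 of 7 p53 targets was lower, 1 of 17 unfolded protein response genes was higher and 1 lower, and the 1 tested blood and stroma marker, Pecam1, was higher. Camera placed the cell cycle, DNA methylation and mRNA clearance lists higher (each adjusted p = 0.031, and adjusted p = 0.834 with an estimated correlation), with 24 of 32, 10 of 12 and 16 of 23 genes positive. The DNA methylation call was lost as TPM (0.069) and without wild-type replicate 1 (0.063), the mRNA clearance call without wild-type replicate 1 (0.13) or knockout replicate 1 (0.0512), and all 3 with the length trend removed. Mitochondrially encoded transcripts were lower in all 13 cases, but none passed in either count (limma; camera adjusted p = 0.13), and their sum varied between libraries (51429 ± 36622 against 28401 ± 3611 FPKM). Wild-type replicate 1 had 21.8% of its FPKM in mitochondrial genes, against 8.30 to 11.8% in the other PN5 libraries. Camera called no other list at PN5 (adjusted p from 0.11 to 0.93), and the subcortical maternal complex (8 tested), NLRP (11), DNA methylation, mRNA clearance, granulosa (2) and sperm (1) lists had no member in either count.

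In 2-cell embryos the knockout differed broadly from wild type: many transcripts of the oocyte were higher and most genes for making ribosomes were lower. Bcl2l10, an oocyte member of the BCL2 family, stood at 725 ± 225 to 5237 ± 1073 FPKM (log2 2.88, SE 0.26, adjusted p = 0.00025). The oocyte linker histone H1foo stood at 26.6 ± 2.87 to 301 ± 121 FPKM (log2 3.38, SE 0.28, adjusted p = 0.00022). Nop16, a factor of large ribosomal subunit assembly, stood at 102 ± 23.4 to 7.25 ± 2.46 FPKM (log2 -3.66, adjusted p = 0.00020). Polr1e, a subunit of RNA polymerase I, stood at 44.8 ± 8.48 to 2.83 ± 0.662 FPKM (log2 -3.58, SE 0.24, adjusted p = 0.00020). Of 13828 tested genes 7513 differed, 1936 higher and 5577 lower (74.2% lower), and 5527 differed at least 2-fold, 1232 higher and 4295 lower. The median tested gene was shifted by -0.44 as deposited, by -0.05 after median-of-ratios rescaling and by -0.56 as TPM. After median-of-ratios rescaling 7153 genes were called, 3326 higher and 3827 lower (53.5% lower). Of the 7513 calls 5763 kept their direction under that scaling and none turned. With the length trend removed, which also takes out each library's overall shift, 50.7% of the calls were lower. Leaving out wild-type replicate 1 gave 4855 calls (1462 higher and 3393 lower), leaving out wild-type replicate 2 gave 5256 (1668 and 3588), and a mean of at least 5 FPKM gave 4052. In the fits without 1 wild-type library, genes detected only in wild type could not be tested.

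The largest rises at the 2-cell stage were in Ninj2, a cell adhesion protein (6.72 ± 3.42 to 95.2 ± 39.2 FPKM, log2 3.68, SE 0.42, adjusted p = 0.00041), AC125178.2 (log2 3.67) and H1foo. Ifitm3 rose from 63.1 ± 9.15 to 512 ± 60.4 FPKM (log2 3.00, SE 0.19, adjusted p = 0.00020) and Sprr2e from 0.988 ± 0.308 to 20.1 ± 8.71 FPKM (log2 3.34). AC165294.1 (log2 3.10), AC104866.2 (2.94) and the mitochondrial ribosomal protein gene Mrpl53 (9.70 to 69.96 FPKM, 2.93) also rose. The largest fall was in Eif3j2 (95.7 ± 17.4 to 11 ± 19.1 FPKM, log2 -4.88, SE 1.18, adjusted p = 0.0084), which is uncertain because of its near-identical copy Eif3j1. The stathmin Stmn3 fell from 45.7 ± 7.72 to 1.68 ± 0.399 FPKM (log2 -4.12, adjusted p = 0.00013) and the arginase Arg1 from 39.7 ± 20.1 to 1.20 ± 0.326 FPKM (log2 -4.11, adjusted p = 0.00022). D5Ertd605e (30.1 to 0.387 FPKM, log2 -4.38), the cystatin Cst7 (57.5 to 3.01 FPKM, -4.04) and Iqub (29.2 to 1.06 FPKM, -3.94) fell. The histone variant gene H2afj (37.2 to 1.94 FPKM, log2 -3.91) and Inka1 (41.6 to 1.90 FPKM, -3.90) followed.

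Most genes of the oocyte identity and NLRP lists were higher at the 2-cell stage. In the oocyte identity list, 18 of 27 genes rose and 2 fell over all genes, and adjusted over the list alone 18 were higher and 3 lower. The median of this list was 0.94 as deposited and 1.39 after median-of-ratios rescaling (19 higher and 1 lower), and its sum was 6851 ± 1109 to 19058 ± 1686 FPKM. Camera gave adjusted p = 2.7e-07, and adjusted p = 0.834 with an estimated correlation. Its members included Oosp1 (919 ± 213 to 2960.0 ± 262 FPKM, log2 1.71, adjusted p = 0.00042) and Tcl1, a coactivator of AKT (468 ± 205 to 1923 ± 438 FPKM, log2 2.10, adjusted p = 0.0011). Of 11 oocyte NLRP genes other than Nlrp14, 8 rose in both counts and none fell (median 1.22, camera adjusted p = 1.6e-05, and adjusted p = 0.834 with an estimated correlation). They included Nlrp9a (41.6 ± 11.9 to 135 ± 3.22 FPKM, log2 1.72, adjusted p = 0.00079), Nlrp4e (26.4 to 86.4 FPKM) and Nlrp4a (25.3 to 78.6 FPKM). Members of the Nlrp4 and Nlrp9 families are similar in sequence, so their separate values are uncertain. Of 8 genes of the subcortical maternal complex 4 rose in both counts. These were Zbed3 (432 ± 177 to 1487 ± 312 FPKM, log2 1.83, adjusted p = 0.0013), Ooep (24.1 ± 13.1 to 133 ± 75.5 FPKM, log2 2.39, adjusted p = 0.0027), Nlrp4f (29.9 to 122 FPKM) and Nlrp2 (4.31 to 10.3 FPKM). The camera call of that complex (adjusted p = 0.031, and adjusted p = 0.834 with an estimated correlation) was lost without wild-type replicate 3 (0.177).

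Most genes of ribosome production and many of the proteasome were lower at the 2-cell stage. Of 43 ribosome biogenesis genes 40 fell and none rose over all genes, and 41 were lower adjusted over the list alone. Their median was -1.73 as deposited and -1.18 after median-of-ratios rescaling (34 lower), and their sum was 1717 ± 245 to 512 ± 36.0 FPKM. Camera gave adjusted p = 1.5e-08, and adjusted p = 0.834 with an estimated correlation. The small subunit assembly factor Ltv1 fell from 108 ± 21.5 to 17.0 ± 1.29 FPKM (log2 -2.58, adjusted p = 0.00020) and the pseudouridine synthase Dkc1 from 63.0 ± 8.44 to 11.8 ± 0.232 FPKM (log2 -2.31, adjusted p = 0.00021). Of 76 cytosolic ribosomal protein genes 62 fell over all genes, and adjusted over the list alone 64 were lower and 1 higher. Their median was -1.16, or -0.72 after rescaling (43 lower and 2 higher), with camera adjusted p = 3.9e-07 and adjusted p = 0.834 with an estimated correlation. Rps29 (20.7 to 4.26 FPKM, log2 -2.03), Rpl39 (24.5 to 5.05 FPKM, -2.07), Rpl14 (28.2 to 7.02 FPKM, -1.87) and Rps4x (32.9 to 8.59 FPKM, -1.80) fell. Of 34 proteasome genes 22 fell and 3 rose over all genes, 23 and 3 adjusted over the list alone (median -1.28, or -0.79 after rescaling, with 17 lower and 5 higher). Psmb1 fell from 48.6 ± 4.79 to 5.76 ± 2.04 FPKM (log2 -2.92, adjusted p = 0.00025), and Psmd14 (48.9 to 7.20 FPKM), Psmb4 (29.2 to 3.99 FPKM) and Psmd12 (75.8 to 12.2 FPKM) fell too. The proteasome's camera call (adjusted p = 0.031, and adjusted p = 0.834 with an estimated correlation) was lost without knockout replicate 1 (0.0521).

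Nuclear genes of the mitochondrial respiratory chain were lower in many cases. Of 60 oxidative phosphorylation genes 34 fell and 4 rose over all genes, 36 and 6 adjusted over the list alone (median -0.96, camera adjusted p = 0.20). After median-of-ratios rescaling 16 were lower and 12 higher (median -0.44). Ndufa9 fell from 47.7 ± 7.95 to 7.04 ± 2.05 FPKM (log2 -2.62, adjusted p = 0.00028), as did the complex III subunits Uqcrc1 (11.5 to 1.03 FPKM) and Uqcrfs1 (37.9 to 6.79 FPKM). For the 13 mitochondrially encoded transcripts the direction depended on scaling, with a median of -0.18 and 1 positive as deposited but 0.36 and 12 positive after rescaling (camera adjusted p = 0.999). Of these mt-Nd6 fell over all genes (1149 ± 277 to 722 ± 18.1 FPKM, log2 -0.64, adjusted p = 0.023) and none passed adjusted over the list alone. That call was lost on rescaling (0.76) and without knockout replicate 1 (0.0536) or 3 (0.073). The antioxidant list had 9 of 19 genes lower and 3 higher in both counts (median -0.63, camera adjusted p = 0.53; 8 and 4 after rescaling), with Prdx4 at 125 ± 25.5 to 25 ± 5.71 FPKM (log2 -2.28, adjusted p = 0.00030). Of 17 p53 targets and apoptosis genes 13 fell and 1 rose in both counts (median -1.08, camera adjusted p = 0.13). After rescaling 8 were lower and 2 higher (median -0.67), and with the length trend removed 7 and 2. The cell cycle inhibitor Cdkn1a (9.34 ± 2.36 to 1.83 ± 0.339 FPKM, log2 -1.85, adjusted p = 0.00074) fell, and Casp8 rose (2.83 to 14.4 FPKM, 1.94). In the unfolded protein response list 12 of 20 fell and 1 rose over all genes, 13 and 1 adjusted over the list alone (median -1.17, camera adjusted p = 0.19; 11 and 2 over all genes after rescaling). The gene that rose was Ddit3, which encodes the stress factor CHOP (21.9 ± 2.90 to 54.2 ± 6.85 FPKM, log2 1.27, adjusted p = 0.0013), while the chaperones Pdia4 (68.0 to 26.2 FPKM) and Sdf2l1 (58.1 to 25 FPKM) fell. Unlike camera, fry placed the oxidative phosphorylation and p53 lists (each adjusted p = 0.012), the antioxidant list (0.0076) and the unfolded protein response list (0.031) lower. These fry values are as deposited, where the median tested gene was itself shifted by -0.44.

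Genes of the embryonic programme went both ways at the 2-cell stage. Of 34 2-cell-specific genes 12 rose and 6 fell in both counts, with a median of 0.58 (23 higher and 5 lower after median-of-ratios rescaling). The camera test gave adjusted p = 0.00092, and adjusted p = 0.834 with an estimated correlation. Gm4027 rose (347 ± 67.3 to 844 ± 149 FPKM, log2 1.28, adjusted p = 0.0016), as did BC061212 (2.61 to 14.3 FPKM), while Tdpoz4 (48.4 ± 15.0 to 5.45 ± 3.91 FPKM, log2 -3.05, adjusted p = 0.00076) and Tdpoz2 (10.4 to 1.31 FPKM) fell. These genes have many near-identical copies, so single values are uncertain. Of 18 embryonic transcription factors 11 fell and 5 rose in both counts (median -1.37), and 10 and 5 after rescaling. Camera did not call this list (adjusted p = 0.56), while fry placed it lower (adjusted p = 0.016). Obox8 fell from 240.0 ± 50.3 to 21.6 ± 11.2 FPKM (log2 -3.51, adjusted p = 0.00028), uncertain because of its homeobox relatives. The ETS factor Gabpa fell from 112 ± 24.8 to 22.9 ± 5.51 FPKM (log2 -2.24, adjusted p = 0.00038), Klf5 from 21 to 5.79 FPKM and Klf4 from 10.9 to 2.95 FPKM. In the cell cycle list 18 of 34 fell and 7 rose over all genes, 18 and 8 adjusted over the list alone (10 and 10 after rescaling, camera adjusted p = 0.999). Cks2 (1068 ± 191 to 3279.9 ± 355 FPKM, log2 1.63, adjusted p = 0.00042) and cyclin Ccnb2 (36.6 to 116 FPKM) rose, and the spindle kinesin Kif11 (15.3 ± 1.41 to 2.22 ± 1.12 FPKM, log2 -2.40, adjusted p = 0.00051) and Sgo2a (17.4 to 4.09 FPKM) fell.

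Maternal mRNA clearance, DNA methylation and calcium genes went both ways at the 2-cell stage, and the sign of each list's median turned with scaling. Of 25 clearance genes 8 rose and 9 fell over all genes, 10 and 9 adjusted over the list alone (median -0.13, mean -0.04, camera adjusted p = 0.20). After median-of-ratios rescaling 11 were higher and 4 lower (median 0.29), and with the length trend removed 11 and 2. The deadenylation adaptor Btg4 rose (1217 ± 418 to 3892 ± 190.0 FPKM, log2 1.73, adjusted p = 0.00082) and the terminal uridylyltransferase Tut7 fell (2.89 to 0.662 FPKM, -1.22). Of 13 genes of DNA methylation and imprint maintenance 4 rose and 4 fell in both counts (median -0.17, mean 0.05, camera adjusted p = 0.29), against 6 and 1 after rescaling (median 0.25) or with the length trend removed. Dppa3, which protects the maternal genome from demethylation, rose from 5303 ± 804 to 16965 ± 3122 FPKM (log2 1.67, adjusted p = 0.00041), as did the dioxygenase Tet3 (2.42 to 6.25 FPKM). The corepressor Trim28 fell from 10.3 ± 2.17 to 2.52 ± 0.278 FPKM (log2 -1.67, adjusted p = 0.00079). Uhrf1, which recruits DNMT1 to replicating DNA and was chosen in advance, rose from 3.88 ± 1.06 to 8.70 ± 2.61 FPKM (log2 0.98, SE 0.28, adjusted p = 0.016), a call lost without wild-type replicate 1 (0.0575) or knockout replicate 2 (0.0576). At earlier stages Uhrf1 read 25.7 ± 1.97 to 28.1 ± 11 FPKM at GV (adjusted p = 0.98), 32.6 ± 2.93 to 24.4 ± 6.69 FPKM at MII (adjusted p = 0.19) and 23.1 ± 10.6 to 41.6 ± 1.99 FPKM at PN5 (adjusted p = 0.11). Of 23 calcium genes 7 rose and 7 fell in both counts (median -0.03, mean -0.06, camera adjusted p = 0.21), against 10 and 6 after rescaling (median 0.46) and 11 and 5 with the length trend removed. Calmodulin Calm2 fell from 676 ± 46.9 to 218 ± 31.2 FPKM (log2 -1.63, adjusted p = 0.00034) and the calcium uniporter subunit Smdt1 from 18.6 to 7.71 FPKM, and the channel Trpv3 rose from 0.0404 to 1.97 FPKM. Slc8b1, a mitochondrial sodium and calcium exchanger also chosen in advance, was below the filter. Its highest value was 0.159 FPKM, in a wild-type 2-cell library, and outside the wild-type GV and 2-cell groups it was listed at 0.

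Markers of other cell types were measured alongside. Of 5 blood, stroma and oviduct markers 3 fell in knockout 2-cell embryos in both counts (camera adjusted p = 0.21, fry adjusted p = 0.030). They were the globin gene Hba-a1 (54.5 ± 17.6 to 16 ± 4.20 FPKM, log2 -1.70, adjusted p = 0.0017), its near-identical copy Hba-a2 (22.0 to 6.16 FPKM), both uncertain, and Cd74 (15.1 to 1.49 FPKM). The list summed to 137, 78.4 and 75.3 FPKM in the wild-type 2-cell libraries and 31.1, 20.5 and 28.1 FPKM in the knockout ones. At GV it was 36.4 FPKM in wild-type replicate 3 and 1.55 to 3.72 FPKM in the other 5 libraries. Of 4 granulosa and cumulus markers, Serpine2 (7.43 to 16.3 FPKM) and Cyp19a1 (0.759 to 2.71 FPKM) rose and Tnfaip6 fell (25.2 to 4.56 FPKM), in both counts at the 2-cell stage. Of 6 sperm markers 3 fell over all genes, and adjusted over the list alone 3 were lower and 1 higher (camera adjusted p = 0.999). The sperm list summed to 38.9, 35.3 and 40.2 FPKM in wild-type and 23.8, 18.4 and 15.6 FPKM in knockout 2-cell libraries. Ldhc fell from 15.3 to 3.66 FPKM, and Hspa1l had 2.62 ± 1.95 FPKM in wild type and was listed at 0 in all 3 knockout libraries. Tssk6 fell from 6.81 to 1.60 FPKM (adjusted p = 0.044), a call lost on rescaling and without wild-type replicates 1 (0.0517), 2 (0.159) or 3 (0.0572) or knockout replicates 1 (0.121) or 2 (0.079).

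**Figure D2:**
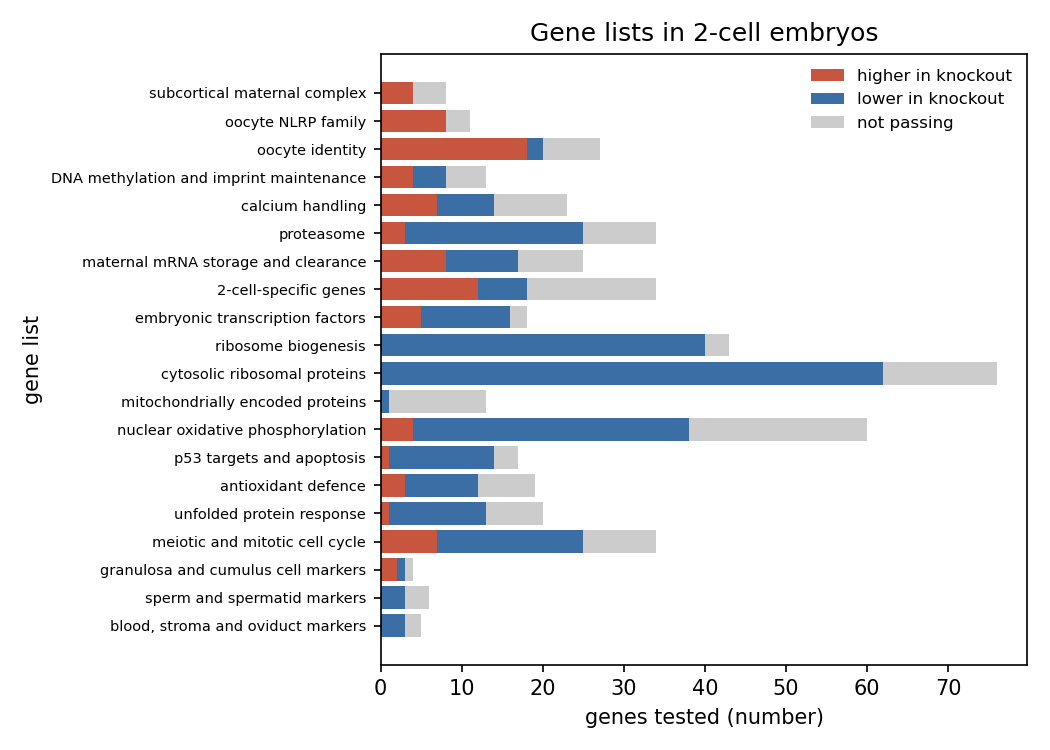
Genes tested in each of the fixed lists at the 2-cell stage (bars, number of genes), divided into those higher, lower and not passing in the knockout at an adjusted p under 0.05. Ribosome biogenesis has 40 of 43 genes lower and oocyte identity 18 of 27 higher, while the mitochondrially encoded transcripts, 1 of 13 lower here, change the sign of their median after median-of-ratios rescaling.

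The changes between stages in wild type give the background to these differences. From GV to MII, 9751 of 11610 tested genes changed, 3616 higher and 6135 lower, with a median of -0.50 (-0.22 after median-of-ratios rescaling). With 1 GV library left out, genes detected only at GV could no longer be tested, which lowers the number of falls. Without wild-type GV replicate 1 the calls were 3436 higher and 3541 lower. They were 3414 and 3566 without replicate 2 and 3384 and 3542 without replicate 3. Lower genes also outnumbered higher ones after rescaling (5505 lower and 4382 higher) and with a mean of at least 5 FPKM (2978 and 2171). Fcf1, a ribosome biogenesis factor, fell from 346 ± 11.1 to 1.65 ± 0.654 FPKM (log2 -7.07, adjusted p = 2.3e-08) and Elobl from 5641 ± 178 to 55.6 ± 8.93 FPKM (log2 -6.65, adjusted p = 8.3e-09). Cpsf4l (352 to 2.20 FPKM), AC132133.2 (145 to 0.358 FPKM) and Acot13 (242 to 1.60 FPKM) were the other large falls. The largest rises were in the mitochondrial transfer RNA genes mt-Tr (5.22 ± 1.43 to 63.2 ± 11.7 FPKM, log2 3.38, adjusted p = 1.4e-06), mt-Tl1 (73.3 to 720.0 FPKM), mt-Ti (13.7 to 133 FPKM) and mt-Tk (5.39 to 50.8 FPKM). These genes are short and adjoin other mitochondrial genes, so their values are uncertain, as is the rise of the Ptp4a1 model ENSMUSG00000117310 (1.10 to 11.9 FPKM). From MII to PN5, 1335 of 9375 genes changed, 919 higher and 416 lower (31.2% lower, and 44.1% after rescaling). Mos, the kinase that holds the MII arrest, fell from 971 ± 37.8 to 25 ± 9.15 FPKM (log2 -5.28, SE 0.25, adjusted p = 0.00046). Plat (797 ± 58.1 to 46.6 ± 19.5 FPKM, log2 -4.14), the lamin B receptor gene Lbr (118 to 8.50 FPKM), Astl (65.5 to 5.86 FPKM) and Saraf (80.9 to 8.32 FPKM) followed. The arginase Arg2 rose from 10.002 ± 1.06 to 167 ± 46.6 FPKM (log2 3.89, adjusted p = 0.00081), as did the vault RNA Vaultrc5 (2.42 to 79.4 FPKM), the clock repressor Nr1d1 (1.41 to 26.2 FPKM) and Elobl (55.6 to 498 FPKM). The rise of the histone gene Hist2h2aa1 (2.05 to 35.0 FPKM) is uncertain because of its copies. The MII to PN5 count was 496, 421 and 443 without wild-type MII replicates 1, 2 and 3, 360 and 2632 (1264 higher and 1368 lower) without wild-type PN5 replicates 2 and 3, and 597 with no filter on low values.

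From PN5 to the 2-cell stage, when the mouse embryo's own genome becomes active, 8418 of 13398 genes changed in wild type, 6429 higher and 1989 lower (23.6% lower, and 36.6% after rescaling). The median was 0.70 as deposited and 0.29 after rescaling. The homeobox gene Obox6 rose from 0.0696 ± 0.120 to 532 ± 96.1 FPKM (log2 8.95, adjusted p = 1.8e-07) and Trim43b from 0.0563 to 327 FPKM. Prps1, an enzyme of nucleotide synthesis, rose from 1.06 ± 1.13 to 496 ± 15.6 FPKM (log2 8.06, adjusted p = 1.7e-06). Rfpl4b and Obox8 were listed at 0 in the 3 wild-type PN5 libraries and reached means of 244 and 239.95 FPKM. The Obox and Trim43 families have near-identical members, so these values are uncertain. H1foo fell from 1284 ± 80.9 to 26.6 ± 2.87 FPKM (log2 -5.54, adjusted p = 6.5e-07) and Oas1d from 2452 ± 343 to 106 ± 26.6 FPKM (log2 -4.54, adjusted p = 3.2e-06). Rgs2 (470.0 to 14.2 FPKM), Obox2 (4107 to 135 FPKM) and Speer4f2 (32.2 to 0.568 FPKM) fell too. In fits without 1 wild-type 2-cell library, genes detected only at the 2-cell stage could not be tested. Without wild-type 2-cell replicates 1, 2 and 3 the count was 3656 (2340 higher and 1316 lower), 3907 (2443 and 1464) and 4251 (2692 and 1559). Without wild-type PN5 replicate 2 it was 7284 (5977 and 1307), and with a mean of at least 5 FPKM it was 4175 for this change and 5149 for GV to MII.

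Whether a change between stages differed by genotype was tested as an interaction. From GV to MII, 15 of 12478 genes differed in their change, 6 more positive and 9 more negative in the knockout (60% negative, and 40% after rescaling). Smap1 went from 12.5 ± 2.54 to 3.17 ± 0.906 FPKM in wild type and 7.13 ± 0.0963 to 14.7 ± 5.52 FPKM in the knockout (log2 interaction 2.59, SE 0.35, adjusted p = 0.015). Ndufa1 went from 93.4 to 19.8 FPKM in wild type and 133 to 3.91 FPKM in the knockout (-2.49, adjusted p = 0.041). Zglp1 (2.19), Tmem243 (2.02) and Mtus1 (1.74) were the others selected. The count was 1 without wild-type GV replicate 1 or 2, 2 without wild-type GV replicate 3, wild-type MII replicate 1 or knockout MII replicate 3, 4 without wild-type MII replicate 2 and 121 without knockout GV replicate 3. It was 46 with no filter and 7 with a mean of at least 5 FPKM. From MII to PN5, 759 of 10190 genes differed, 291 more positive and 468 more negative. They included Lpcat1 (2.96), Srsf4 (2.69, SE 0.69, adjusted p = 0.0478), Dcbld2 (2.68) and Atxn2l (2.67). In the other direction they included Vaultrc5 (-2.77), Smap1 (-2.55), Pard3bos2 (-2.47, adjusted p = 0.037) and Iglv1 (-2.28). The limma count was 0 without any one of the 3 wild-type MII libraries, knockout MII replicate 3, wild-type PN5 replicate 2, knockout PN5 replicate 2 or knockout PN5 replicate 3, with 3082 to 3534 genes at an unadjusted p under 0.05. It was 1 without knockout PN5 replicate 1, 3 without knockout MII replicate 2, 50 without wild-type PN5 replicate 1, 2693 without knockout MII replicate 1 and 4130 without wild-type PN5 replicate 3.

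From PN5 to the 2-cell stage, 6860 of 14986 genes differed in their change, 2073 more positive and 4787 more negative in the knockout, with a median of -0.43 (-0.25 after rescaling). Ninj2 went from 46.5 ± 14.1 to 6.72 ± 3.42 FPKM in wild type and 22.0 ± 3.50 to 95.2 ± 39.2 FPKM in the knockout (log2 interaction 4.68, SE 0.54, adjusted p = 0.00012). The RNA polymerase I factor gene Cd3eap went from 2.67 to 16 FPKM in wild type and 8.74 to 1.17 FPKM in the knockout (-4.51, SE 0.56, adjusted p = 0.00015). Nudt22 went from 0.335 to 49.5 FPKM in wild type and 0.628 to 2.60 FPKM in the knockout (-4.16, adjusted p = 7.7e-05). The others selected were AC165294.1 (4.82), AC125178.2 (4.34), AC104866.2 (4.07), D5Ertd605e (-4.38) and Eif3j2 (-5.83, uncertain). The Eif3j2 call (adjusted p = 0.031) was lost without wild-type PN5 replicates 1 or 2, knockout PN5 replicates 1 or 3, or replicates 1 or 2 of either 2-cell group (0.0543 to 0.0778). Nlrp14 had an interaction of 2.75 (SE 0.38, adjusted p = 0.00025). It fell to 50.5% of its PN5 level in wild type and rose 3.89-fold in the knockout (log2 1.77, SE 0.27, adjusted p = 0.00072). Without wild-type 2-cell replicate 1 the count was 4817 (1742 more positive and 3075 more negative), and with a mean of at least 5 FPKM it was 2892.

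Wild-type stage genes were then followed in the knockout, with the compared wild-type library left out of their definition. With that library out, genes under 1 FPKM in every PN5 library could not reach the filter of 3 libraries. The rising genes followed here were thus already at 1 FPKM or more in some PN5 library. The full fit had 5762 rises and 1482 falls of at least 2-fold. Genes that rose at least 2-fold from PN5 to the 2-cell stage, 2258 to 2591 of them depending on the library left out, lay lower in knockout 2-cell embryos by medians of -1.43, -1.22 and -1.06. Of these genes 89.7 to 91.1% were lower. Genes that fell, 1228 to 1422, lay higher by medians of 0.86, 0.66 and 0.68. The remaining wild-type libraries differed from the one left out by -0.22, 0.10 and 0.22 for the rising and by 0.13, -0.18 and -0.20 for the falling genes. In the knockout the median change was 51.5 to 53.6% of the wild-type change for rising genes and 41.7 to 50.2% for falling genes. These shares are not fully held out. The wild-type PN5 libraries that helped to pick the genes also entered the wild-type change, but not the knockout change. The wild-type change may therefore be overstated and the shares too low. From GV to MII the corresponding medians were -0.23 to -0.29 for rising genes and -0.02 to -0.04 for falling genes, and after median-of-ratios rescaling their means turned to 0.08 and 0.09.

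**Figure D3:**
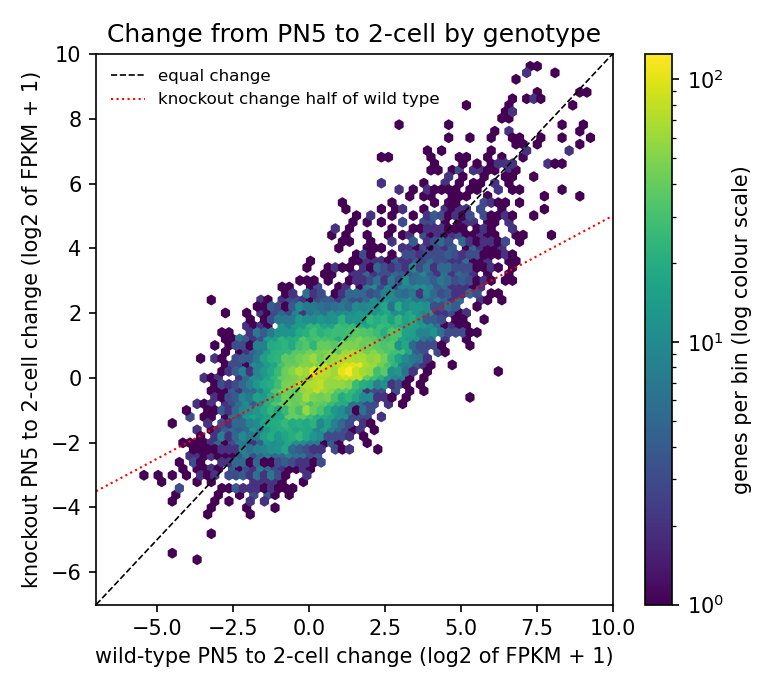
Change from PN5 to the 2-cell stage for 13398 genes, wild type on the horizontal and knockout on the vertical axis (log2 difference of FPKM + 1), with the number of genes shown by shade, a dashed line of equal change and a red dotted line of slope 0.5. The cloud lies flatter than the dashed line, and across genes, which are not independent, Spearman's rho is 0.593.

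Calls were compared between stages, whose libraries are separate. Apart from Nlrp14, 48 genes were lower in the knockout at both MII and PN5, against 8.48 for independent lists, and none of the genes lower at MII was higher at PN5. At both MII and the 2-cell stage 61 genes were lower (44.2 for independent lists) and 11 higher (4.70). At both PN5 and the 2-cell stage 124 were lower (156 for independent lists), while 128 of the genes lower at PN5 were higher at the 2-cell stage. For calls in opposite directions no value for independent lists was computed, so neither the 128 nor the lack of such genes between MII and PN5 is set against one. The 128 came from 503 genes lower at PN5 and 1632 higher at the 2-cell stage, of 8681 tested in both. Between MII and PN5 there were 152 genes lower at MII and only 52 higher at PN5, of 8386 tested in both. Spearman's rho of the log2 differences, across genes, which are not independent, was 0.54 between GV and MII, -0.35 between MII and PN5, 0.16 between MII and the 2-cell stage and -0.13 between PN5 and the 2-cell stage. With a mean of at least 5 FPKM the shared lower genes numbered 16 for MII and PN5 and 20 for MII and the 2-cell stage, and the shared higher genes 5.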

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

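The tests chosen only after the result was seen were, in this part, both tests on Nlrp14, the test of the length trend as the whole of the PN5 difference, the setting of the length test beside other rescalings, the test of an incomplete passage to the 2-cell stage and the alternatives with the length trend removed or with values rescaled to TPM.

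The effect of genotype differed between successive stages, by the interaction test, in 15 genes from GV to MII, 759 genes from MII to PN5 and 6860 genes from PN5 to the 2-cell stage, and in Nlrp14 itself from PN5 to the 2-cell stage (log2 interaction 2.75). Of 100 splits drawn from the 200 splits of the 12 libraries within their stages, 2 gave at least 15 genes from GV to MII, the real one included (highest other 16), 2 gave at least 759 from MII to PN5 (highest other 1556) and 1 gave at least 6860 from PN5 to the 2-cell stage (highest other 6025). These shares lay under the bound of 0.05 set in advance. Only from PN5 to the 2-cell stage did no other drawn split reach the real count. From GV to MII and from MII to PN5 another split gave more genes, so chance is not excluded for those counts. In each of these 3 comparisons the highest other split kept the genotypes apart at the later stage and mixed them at the earlier one. The 1556 genes of such a split point to a structure of the samples, which put knockout PN5 replicates 1 to 3 with wild-type MII replicate 1 and knockout MII replicates 2 and 3.

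At PN5, 524 genes were lower in the knockout, of which 5.15% (27 of 524) stayed called lower once each library's length trend was removed. Loss of these calls was not particular to length, since 11 stayed called lower after median-of-ratios rescaling (median log2 difference -1.24, median SE 0.29) and 6 as TPM (-1.22, median SE 0.30). A length trend as part of the difference therefore stays open. With the trend removed their median log2 difference went from -1.25 (median SE 0.25) to -1.03 (median SE 0.23), and 517 kept an unadjusted p under 0.05. There the calls ended for 2 reasons: the genes' median p rose from 0.0012 to 0.0038, and the largest p that still passed fell from 0.0030 to 0.00022. With the earlier limit of 0.0030, 225 of the 524 would have passed. The interquartile range around the median of -1.03 was -1.28 to -0.78, with all 522 genes of known length below 0. These genes had been picked as lower in the same libraries. Their values therefore cannot decide whether the trend is the whole of the difference. Their median of -1.13 without wild-type replicate 1 is bound by the same choice. A new fit without that replicate, however, called 616 genes, 534 of them lower, which argues against wild-type replicate 1 alone. A later start of embryonic transcription in the knockout gained no support, though it was not excluded. In wild type the lower genes rose from MII to the 2-cell stage 1.01 times as often as matched sets. The shares were 32.0% against a median of 31.6%, with 4476 of 10000 sets at or above. This ratio fell short of the one set in advance for this cause, but the share was not at or below the median, the bound against it. A difference of the genotypes at PN5 that is independent of these stays open too, as untested.

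At the 2-cell stage, differences in scaling between libraries may account for part of the 7513 calls, since 76.7% stayed called in the same direction after median-of-ratios rescaling and 73.3% with the length trend removed, while none turned. Both shares lie between the bounds set in advance for a cause (under 50%) and against it (at least 80%), which keeps them open. An incomplete passage from PN5 to the 2-cell stage stays open as a hypothesis. At least 78.4% of wild-type stage genes were displaced towards PN5 in each of the 3 held-out libraries and both directions, but this share had been seen before its bound was set, so it adds no support. The age of the embryos at collection was not given in the sources used here, so a delay and an arrest were not separated.

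Nlrp14 rose 3.89-fold from PN5 to the 2-cell stage in the knockout while it fell in wild type. Whether loss of other maternal RNA raised its share was not decided. Of the genes that fall at least 2-fold in wild type, only 1.95% (28 of 1436) rose as much in the knockout, where their median ratio was 0.513. These genes were picked because they fall, so they cannot show how far a retained RNA would gain in share. Nlrp14 itself, at 50.5% of its PN5 level in wild-type 2-cell embryos, was outside that set. The bound was also set after the values were seen. Transcription from an intact allele in the embryo could give the interaction of 2.75 and stays open, because the genotype of the males and reads per exon were not used here.

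For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and in each the real split was the 1 with a count as large. The real count and the highest of the other splits were 5 and 1 at GV, 199 and 0 at MII, 578 and 1 at PN5 and 7513 and 0 at the 2-cell stage, and 9751 and 0, 1335 and 1 and 8418 and 0 for the wild-type changes from GV to MII, MII to PN5 and PN5 to the 2-cell stage. For the gene lists, 25 of 100 splits gave at least as many called lists as the real 18 (highest other 27), so chance is not excluded for their number.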

How the results depend on the processing

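The alternatives chosen only after the data were seen were, in this part, removal of the length trend and rescaling to TPM. Of 2942 values of 202 named gene results under the alternatives, 2312 kept their direction and their side of the threshold, 622 lost the call, 4 gained one and 4 reversed. The number that kept them was 1313 of 1330 at the 2-cell stage, 191 of 339 at MII and 204 of 520 at PN5, and no value for the wild-type changes was lost. For 18 called lists, 182 of 234 values kept the call. The reversed gene was Uhrf1 at GV, which was not called: 0.04 as reported, -0.0451 as TPM, -0.01 without wild-type replicate 3, -0.14 and -0.15 without knockout replicates 1 and 2, and 0.41 without knockout replicate 3. The held-out medians from GV to MII reversed under median-of-ratios rescaling, to 0.0806 for rising and 0.0886 for falling genes, since that rescaling shifts all genes of a library together. At GV the count of 5 was 2 with no filter, 1 with a mean of at least 5 FPKM, 197 with all 24 libraries in one fit and 35 with the length trend removed. At MII the count of 199 was 65 under median-of-ratios rescaling, 8 with no filter, 63 with a mean of at least 5 FPKM, 69 with a pseudocount of 0.1, 132 with a 2-fold threshold and 128 with the length trend removed. At PN5 the count of 578 was 15 under median-of-ratios rescaling, 3 with no filter, 110 with a pseudocount of 0.1, 2491 with all 24 libraries in one fit, 41 with the length trend removed and 7 as TPM. A mean of at least 5 FPKM, which tests fewer genes, gave 4052 calls at the 2-cell stage and 5149, 768 and 4175 for the wild-type changes from GV to MII, MII to PN5 and PN5 to the 2-cell stage, and no filter gave 597 for MII to PN5. The interaction from GV to MII (15) had 46 calls with no filter and 7 with a mean of at least 5 FPKM, that from MII to PN5 (759) had 13 with no filter and 88 with a pseudocount of 0.1, and that from PN5 to the 2-cell stage (6860) had 2892 with a mean of at least 5 FPKM. With that mean, shared calls were 16 lower for MII and PN5 and 5 higher and 20 lower for MII and the 2-cell stage. Leaving out 1 library gave 1 to 1026 calls at GV, 3 to 3083 at MII, 1 to 2967 at PN5, 4855 to 6606 at the 2-cell stage, 6926 to 9278, 360 to 2632 and 3656 to 8459 for the wild-type changes and 1 to 121, 0 to 4130 and 4817 to 7372 for the interactions, where the limma count of 0 had 3082 to 3534 genes at an unadjusted p under 0.05. The lowest and highest counts were without any one wild-type replicate and without knockout replicate 3 at GV, and without wild-type replicate 1 and knockout replicate 1 at MII. At PN5 the lowest was without wild-type replicate 2, knockout replicate 1 or knockout replicate 3 and the highest without wild-type replicate 3. For the wild-type change from MII to PN5 they were without wild-type PN5 replicates 2 and 3, and the lowest counts at and up to the 2-cell stage were without wild-type 2-cell replicate 1. For the interactions they were without wild-type GV replicate 1 or 2 and knockout GV replicate 3 from GV to MII and, for the highest count from MII to PN5, wild-type PN5 replicate 3. Of 18 lists called by camera with a preset correlation, 0 were called with an estimated one (3 of 69 at an unadjusted p under 0.05), fry called 18 of which 9 were the same, 16 were called under median-of-ratios rescaling or as TPM, 13 with the length trend removed and 15 to 19 without 1 library. Apart from smaller numbers of genes tested or libraries left in, the cause was not tested. Depth limits genes near 0.131 FPKM in 1 kb, the largest value of a single fragment, and knockout 2-cell libraries were the shallowest on average.

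The replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.19, 0.21 and 0.11 at GV, -0.21, 0.01 and -0.11 at MII, -0.02, 0.01 and -0.01 at PN5 and -0.01, -0.07 and -0.17 at the 2-cell stage, and only number 3 at GV correlated best with its own number. With the replicate block the counts were 2 at GV, 132 at MII, 1 at PN5 and 7011 at the 2-cell stage, 2, 2 and 6593 for the interactions and 17 for the lists.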

Other observations

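All genes in this part were chosen after their values were seen, and no test in it was planned. Some genes of knockout 2-cell embryos lay outside the range between wild-type PN5 zygotes and wild-type 2-cell embryos. As deposited, 385 genes were at least 2-fold above both wild-type groups and 243 at least 2-fold below both, with both differences called. Among those above were Cfl1, the actin-severing protein cofilin, with 171 ± 34.0 FPKM against 47.9 ± 5.43 and 66.8 ± 11.5 FPKM in wild-type PN5 and 2-cell samples (n = 3 each). Ifitm3 had 512 ± 60.4 FPKM against 158 ± 4.79 and 63.1 ± 9.15 FPKM, the polycystin family channel Pkd2l2 646 ± 72.9 FPKM against 237 ± 28.8 and 251 ± 79.3 FPKM, and Mapk3, the kinase ERK1, 49.6 ± 7.24 FPKM against 15.1 ± 6.33 and 19.8 ± 9.33 FPKM. The retinoic acid enzyme Aldh1a2 (18.8 against 5.23 and 2.46 FPKM), Umodl1 (167 against 57.0 and 40.9 FPKM), the coatomer subunit Copz1 (62.5 against 20.2 and 21.3 FPKM) and the proton pump subunit Atp6v0c (52.7 against 15.0 and 16.3 FPKM) followed. Several replication-dependent histone genes were above both as well, such as Hist1h4c (22.3 against 6.24 and 6.84 FPKM) and Hist1h2bj (33.0 against 10.9 and 11.5 FPKM), which are uncertain because of near-identical copies.

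Among the genes below both wild-type groups were the chaperonin subunit Cct8 (21.8 ± 2.47 FPKM against 89.7 ± 5.62 and 85.5 ± 22.2 FPKM) and the chaperone Hsp90ab1 (14.7 ± 6.47 FPKM against 57.7 ± 22.9 and 52.0 ± 17.9 FPKM). Splicing factors (Sf3a1, 1.65 against 14.9 and 12.6 FPKM, and Smu1, 31.1 against 266 and 114 FPKM), the nuclear pore gene Nup107 (2.12 against 21.8 and 18.1 FPKM) and the translation factor Eif5b (6.92 against 32.8 and 26.9 FPKM) were lower. So were genes of DNA replication and division: the kinase Cdc7 (1.02 against 9.09 and 7.02 FPKM), Gins1 (2.64 against 12.3 and 11.1 FPKM), the kinetochore gene Ndc80 (4.48 against 35.5 and 17.6 FPKM) and the midzone protein Prc1 (5.92 against 25.6 and 22.8 FPKM). Trp53, which encodes p53, stood at 1.82 ± 1.36 FPKM against 8.61 ± 4.26 and 7.54 ± 1.08 FPKM. These groups were read from the listed genes and were not tested for enrichment.

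Only Nlrp14 and the noncoding RNA Gm30564 were lower in the knockout at all 4 stages, and 23 genes were lower at MII, PN5 and the 2-cell stage. Besides predicted genes these include the respiratory chain genes Ndufa1 and Uqcr11, the hypoxia-induced Hilpda, the nucleosome-binding Hmgn5 and the zinc finger genes Zfp992, Zfp994, Zfp820 and Zfp345, which belong to large families of similar genes and are uncertain.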
